A study of Mus musculus with 15 samples.

How the data were processed

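Counts per gene were analysed for 15 polyadenylated RNA libraries, prepared with a stranded Illumina mRNA kit per the labels' protocols, from mouse lines of CD1 background. The deposited values are whole-number read counts per gene under Ensembl gene identifiers, in 1 table for the retroviral lines and 1 for the lentiviral lines. The submitters call these tables filtered, and what was filtered is not given in the sources used here. Per the submitters' processing notes, Trimmomatic 0.39, FastQC 0.11.7, HISAT2 2.1.0, SAMtools 1.9 and HTSeq 0.11.2 were used with the mouse build mm10. The gene annotation and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes are uncertain.

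The 5 summary rows that HTSeq adds were left out of library sizes and tests. Genes took 68.8% to 77.0% of all entries of a library, reads with no unique alignment 3.95% to 7.35% and reads not aligned 3.55% to 12.14%. Of 43432 gene identifiers, 42462 were matched to a symbol and 42548 to a position in GENCODE M21 (GRCm38, the same assembly as mm10), and 14907 had no count in any library, so genes without counts were still listed. Libraries held 34916933 to 75376275 counts in genes. A count of 0 allows up to 3 counts, 0.0386 to 0.0848 CPM. The retroviral libraries were shallower than the lentiviral ones, so their low genes are measured less precisely.

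Groups were taken from the sample labels, with 5 libraries each. Comparisons, tests, most alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Gene tests used edgeR 4.0.16 in R 4.3.3: trimmed mean of M values (TMM) scaling, the filterByExpr filter with a minimum count of 10, the quasi-likelihood F test and Benjamini-Hochberg adjustment, with a threshold of 0.05. Fold changes are lentiviral SKM over lentiviral OSKM and retroviral OSKM over lentiviral OSKM, each fitted on its own 10 libraries. Standard errors are the log2 fold change divided by the square root of F. Both comparisons use the lentiviral OSKM libraries, so no overlap between them was computed. In the retroviral comparison library series and group are the same split, and no batch term could be fitted.

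The 31 gene lists held 506 entries, 502 of them matched. Genes said to pass over the list alone had their p-values adjusted within 1 list, with no adjustment across lists. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Marker levels are medians over the members of a list of log2(CPM + 0.5), with mean and SD per group. Similarity within and between groups used Spearman correlations over all regroupings of the libraries.

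Named genes were, per comparison, the 4 reprogramming factors, the 12 largest rises and 12 largest falls among genes that passed with an average log2 CPM of at least 1 and a symbol that is not a clone name, and up to 4 members of each list that passed. Where fewer than 10 genes passed, the genes with the smallest p were added up to 10. For marker levels, up to 4 members with the highest mean CPM were named from each of 6 lists, with 10 further genes fixed by name. Some genes that this rule selects are not reported here. Members of called lists given as examples beyond this rule were chosen after their values were seen.

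Alternatives were DESeq2 1.42.0, limma voom without and with sample quality weights, robust edgeR, other scalings and filters, a fit of all libraries, the replicate number as a block, a Y-linked covariate, other thresholds, other pseudocounts and summaries, and each library left out in turn. Leaving out libraries in doubt, testing protein-coding genes only and thinning the lentiviral OSKM libraries to the mean retroviral depth were added after the data were seen. The gene and list tests were tested on simulated counts with 200 changed genes in each of 5 runs: 2.6% of calls were false for the 15899 genes of the lentiviral comparison and 3.1% for the 15483 genes of the retroviral comparison. A list planted to change was called in 5 of 5 runs, and 0 other lists were called in runs without it. These runs drew each gene independently, so they do not test list calls where the genes of a list vary together. In other regroupings of the real lines camera called a median of 5 lists in the lentiviral and 6 in the retroviral comparison.

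Near-identical genes were searched with BLAST+ 2.17.0, comparing the longest transcript of each tested pseudogene with all transcripts, at 95% identity over 80% of the length. Chromosome-wide shifts were measured over 9098 genes with a mean of at least 10 CPM, as log2(CPM + 0.5) minus the median of the gene over all lines, centred per library. A chromosome passed at a median of at least 0.25 with all of 5 segments at least 0.1 to the same side. This measure was changed after its first simulated test recovered too little of the planted shift. In the 5 final runs, on 9176 genes, a planted 0.58 was recovered as 0.49 to 0.57. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.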

Results

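Polyadenylated RNA was sequenced from 15 mouse lines obtained by reprogramming embryonic fibroblasts towards induced extraembryonic endoderm stem (iXEN) cells. XEN cells are the self-renewing culture counterpart of the primitive endoderm, the early lineage that forms the yolk sac endoderm. The first 5 lines were cloned from single cells with an active Oct4-EGFP reporter after retroviral delivery of Oct4, Sox2, Klf4 and Myc (retroviral OSKM). A further 5 lines received the same 4 factors by lentivirus (lentiviral OSKM), and the last 5 received the 3 factors Sox2, Klf4 and Myc by lentivirus (lentiviral SKM). Each library was 1 distinct line, and the lentiviral lines were past passage 11 and came from separate fibroblast preparations. Whether the retroviral clones came from separate preparations is not stated, so p-values that involve them measure the spread between clones. The series description calls the lentiviral lines iXEN, whereas the titles of all of them begin with IPS. Other sample fields call all of them except lentiviral OSKM replicate 1 induced pluripotent. The treatment fields of the retroviral lines and of lentiviral OSKM replicate 1 speak of embryonic stem cells as the starting cells, so the fibroblast origin given here follows the series description. Counts assigned to genes came to 34916933 to 46995817 in the retroviral OSKM libraries, 64348250 to 73405134 in the lentiviral OSKM libraries and 60998360 to 75376275 in the lentiviral SKM libraries. Between 19399 and 21048 genes were detected per library. A level resting on 3 counts, the most that a count of 0 allows, corresponded to 0.0386 to 0.0848 CPM (library-scaled counts, with TMM factors). That limit covers counting error only.

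The levels of cell type markers addressed which identity the lines carried. XEN regulators and parietal endoderm genes were highly expressed in all 3 groups, visceral endoderm genes less so, and at most 12 of 27 genes of the pluripotent state were above 1 CPM in any line. The median log2(CPM + 0.5) of 12 XEN regulators was 7.46 ± 0.79 (SD, n = 5) in retroviral OSKM, 7.82 ± 0.46 in lentiviral OSKM and 8.25 ± 0.35 in lentiviral SKM lines. The corresponding median of 27 pluripotency genes was −0.29 ± 0.50, −0.46 ± 0.36 and −0.50 ± 0.42. The difference between the lists was 7.75 ± 0.63, 8.28 ± 0.25 and 8.75 ± 0.61 log2 units in the 3 groups. Gata4, a transcription factor that drives primitive endoderm fate, averaged 1029 ± 208 CPM in lentiviral OSKM and 1165 ± 143 CPM in lentiviral SKM lines, and ranged from 559 to 1360 CPM in retroviral OSKM lines. Across the 15 lines its partner Gata6 ranged from 107 to 568 CPM, the endoderm factor Sox17 from 321 to 665 CPM, the receptor Pdgfra from 342 to 786 CPM and the endocytic adaptor Dab2 from 233 to 1150 CPM. Sox7 ranged from 28.8 to 840 CPM. Foxa2 ranged from 2.60 CPM in retroviral OSKM replicate 3 to 195 CPM.

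Parietal endoderm genes, which encode the basement membrane of the outer yolk sac, were the most highly expressed list, with medians of 9.55 ± 0.42 in retroviral OSKM, 9.65 ± 0.55 in lentiviral OSKM and 10.12 ± 0.25 in lentiviral SKM lines (SD, n = 5). The laminin chains Lama1, Lamb1 and Lamc1 ranged from 1820 to 23900, from 3660 to 19600 and from 1050 to 20600 CPM. The type IV collagen chain Col4a1 was at 55.3 CPM in retroviral OSKM replicate 1 and 62.1 CPM in lentiviral OSKM replicate 5, and from 5100 to 32400 CPM in the other lines. Visceral endoderm genes had lower and more variable medians, 1.53 ± 1.37, 0.73 ± 0.86 and 1.41 ± 1.69. Within that list the endocytic receptors Cubn and Lrp2 ranged from 9.76 to 1080 and from 13.7 to 464 CPM, the Hippo pathway scaffold Amot from 45.4 to 433 CPM, and the retinol carrier Rbp4 from 0.465 to 326 CPM.

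Among the pluripotency genes, Nanog, a core factor of the pluripotent state, did not exceed 2.08 CPM in any of the 15 lines. Of 4 members picked out after their values were seen, Esrrb and Fgf4 reached at most 0.195 and 0.0807 CPM, whereas Zfp42 reached 13.4 CPM and was above 1 CPM in 9 of 15 lines, and Dppa5a reached 5.08 CPM and was above 1 CPM in 2. The most abundant members of this list were the RNA-binding protein Lin28a, at 221 to 728 CPM, and the transcription factors Klf5 (91.3 to 423 CPM), Tfcp2l1 (32.1 to 248 CPM) and Tbx3 (42.9 to 168 CPM). Pou5f1, the gene for Oct4, was above 1 CPM in 3 lines, all retroviral. Fibroblast markers, the starting cell type, had medians of −0.31 ± 0.92 in retroviral OSKM, 0.50 ± 2.14 in lentiviral OSKM and 0.90 ± 2.01 in lentiviral SKM lines, with 4.32 in lentiviral OSKM replicate 5 and 3.82 in the highest lentiviral SKM line. The surface glycoprotein Thy1 was highest in lentiviral OSKM replicate 5, at 40.0 CPM. It was above 1 CPM in 3 of 15 lines and above 10 CPM in 2, the others of these being lentiviral SKM lines. Across all lines Col1a2 ranged from 0.256 to 279 CPM, Col6a1 from 4.52 to 190 CPM, Fbn1 from 4.97 to 78.7 CPM and Zeb1 from 14.2 to 63.2 CPM. Trophoblast medians were −0.78 ± 0.15, −0.78 ± 0.19 and −0.90 ± 0.09, and Krt7, Gata3, Plac1 and Eomes stayed at or below 12.5, 7.47, 7.84 and 6.69 CPM. Cdx2, a regulator of trophoblast fate, reached 13.7 CPM in lentiviral OSKM replicate 5. Endothelial and smooth muscle medians lay at 2.61 ± 2.05 and 2.03 ± 0.99 in retroviral OSKM, 2.18 ± 0.61 and 2.58 ± 0.64 in lentiviral OSKM and 1.78 ± 0.66 and 2.31 ± 0.92 in lentiviral SKM lines. Haematopoietic, neural, gut endoderm and germline medians lay between −0.76 and 0.04 in each group. No test between groups was planned for these levels.

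**Figure D1:**
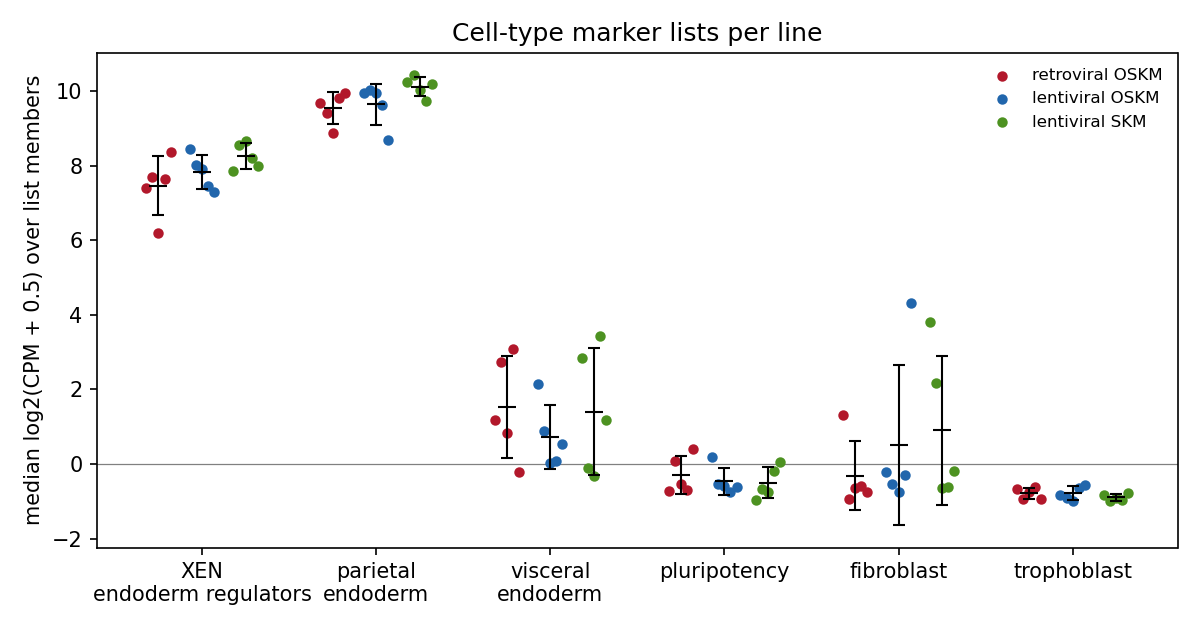
Median log2(CPM + 0.5) of marker lists in each of the 15 lines, by group (retroviral OSKM, lentiviral OSKM, lentiviral SKM); points are lines and bars are group means with SD (n = 5). XEN regulators averaged 7.46, 7.82 and 8.25 and pluripotency genes −0.29, −0.46 and −0.50 in the 3 groups.

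**Figure D2:**
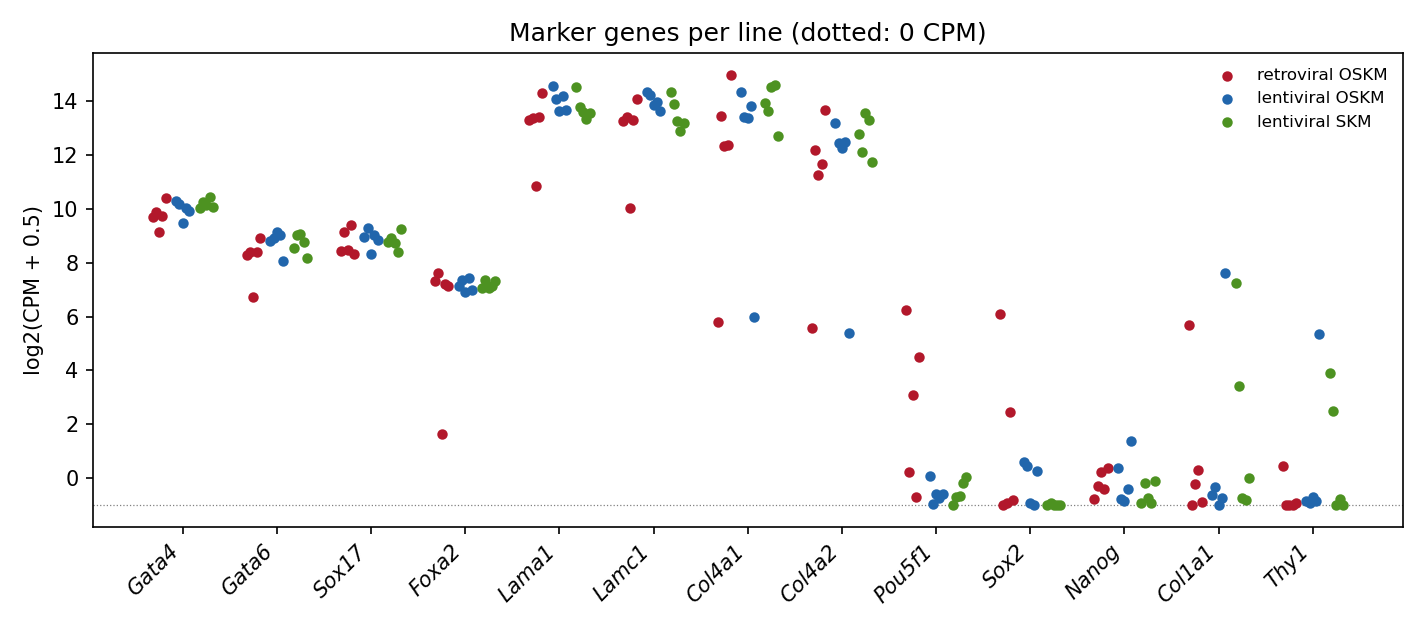
Level of 13 marker genes as log2(CPM + 0.5) in each of the 15 lines, with 1 point per line and groups side by side. Gata4 was at 559 CPM or more in every line, whereas Nanog did not exceed 2.08 CPM.

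The comparison of lentiviral SKM with lentiviral OSKM lines addressed how lines made without Oct4 differ from lines made with it. No single gene passed the test. Camera (limma) with a preset correlation called 4 of 31 gene lists, with most members of the cholesterol synthesis, p53 response and interferon response lists lower and most of the hypoxia and glycolysis list higher in lentiviral SKM lines. None of the 4 calls held with an estimated correlation (adjusted p = 0.879 for each), and 82 of 100 regroupings of the same 10 lines gave at least 4 lists. The 12 XEN regulators were not distinguished, with 8 higher, 4 lower, a median log2 fold change of 0.16 and adjusted p = 0.297 by camera (limma). Among them Sox7 was at 491 CPM in lentiviral SKM against 267 CPM in lentiviral OSKM lines (log2 fold change 0.87, SE 0.50).

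Of the reprogramming factors, endogenous and vector-derived transcripts could not be told apart in counts per gene. Pou5f1, on chromosome 17 from 35506018 to 35510772 (GRCm38), averaged 0.203 CPM in lentiviral OSKM and 0.234 CPM in lentiviral SKM lines, a log2 fold change of 0.20 (SE 1, 95% confidence interval −2.00 to 2.41). Klf4 averaged 229 and 299 CPM (log2 fold change 0.38, SE 0.32, interval −0.33 to 1.09), and Myc 74.5 and 82 CPM (0.13, SE 0.28, interval −0.48 to 0.75). Sox2 reached at most 1.04 CPM in lentiviral OSKM and 0.0329 CPM in lentiviral SKM lines and was too low to be tested.

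Of 15899 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, with a smallest adjusted p of 0.758. At an unadjusted p under 0.05 there were 773 genes, 364 higher and 409 lower in lentiviral SKM lines, where chance gives 795. Both limma voom and voom with sample quality weights also called 0, and DESeq2 called 44, 16 higher and 28 lower. The values of the 2 groups did not overlap for 119 genes, 0.75% of those tested against 0.79% by chance. Spearman correlations between libraries averaged 0.952 within each lentiviral group and 0.952 between them, and the within-minus-between difference of 1e-04 was reached by 56 of 126 regroupings (one-sided exact permutation p = 0.4444). The median 95% interval reached 0.63 log2 units to either side of the estimate. On simulated counts for these 15899 genes the test recovered 22.7% of 2-fold, 54.9% of 4-fold and 79.7% of 8-fold changes, so smaller changes were often not detectable with 5 lines per group.

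The genes with the smallest p-values are given as values, since none passed (adjusted p = 0.758 for each, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The homeobox gene Dlx1 averaged 2.33 CPM in lentiviral OSKM and 0.346 CPM in lentiviral SKM lines (log2 fold change −2.75, SE 0.52). Msx2, another homeobox gene and a target of BMP signalling, had a log2 fold change of −1.84 (SE 0.38), and Isoc1 one of −0.92 (SE 0.18). The antisense transcript Gm15908 and the pseudogene BC002163 had −2.56 (SE 0.45) and −4.65 (SE 0.97). For Gm15908 the strand setting of the counting is not given in the sources used here, so reads from its partner gene on the other strand cannot be excluded. On the higher side, Ndrg1, a hypoxia-induced gene, averaged 137 and 274 CPM (log2 fold change 1, SE 0.21). Arhgap28, a GTPase-activating protein gene, had 0.87 (SE 0.17), Map4k3, a kinase, 0.61 (SE 0.13), and the membrane protein gene Marveld1 1.01 (SE 0.21). Each of these genes lay on 1 side of the lentiviral OSKM mean in 5 of 5 lentiviral SKM lines, and each passed with DESeq2 (adjusted p from 2.44e-05 to 0.0105, and up to 1 for each over all alternatives).

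**Figure D3:**
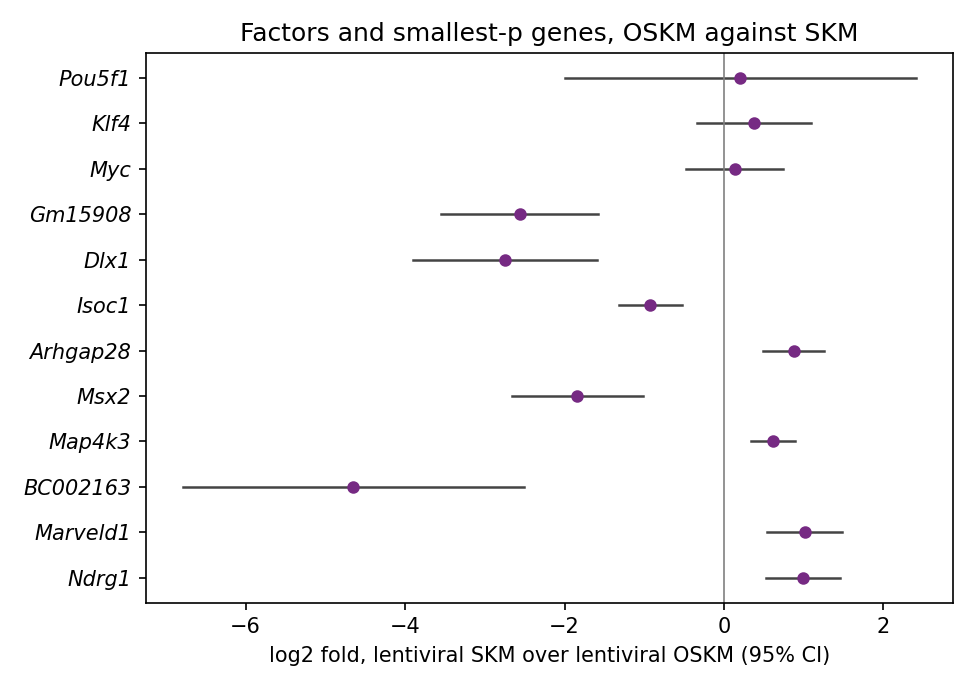
Log2 fold change of lentiviral SKM over lentiviral OSKM lines (n = 5 each) for 12 genes, 3 reprogramming factors and 9 of the genes with the smallest p; points are estimates and bars 95% confidence intervals. None passed at adjusted p under 0.05 with edgeR, and the interval of Pou5f1 runs from −2.00 to 2.41.

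Within the called lists, 19 of 20 genes of cholesterol synthesis were lower in lentiviral SKM lines, with a median log2 fold change of −0.36 (camera adjusted p = 7.16e-06; adjusted p = 0.879 with an estimated correlation). The exception was Insig1, which encodes a brake on the pathway, at 0.51 (SE 0.19). Of 17 genes of the p53 response, 15 were lower (median −0.31, adjusted p = 0.000219; adjusted p = 0.879 with an estimated correlation), among them the death receptor gene Fas at −1.72 (SE 0.59) and the p53-induced nuclease gene Aen at −0.41 (SE 0.15). Of 20 interferon response genes, 17 were lower (median −0.45, adjusted p = 0.000903; adjusted p = 0.879 with an estimated correlation), with the RNA sensor gene Ifih1 at −2.72 (SE 1.19) and Ifit2 at −1.84 (SE 0.76). Without lentiviral OSKM replicate 5, which has the highest fibroblast median, the interferon list no longer passed (adjusted p = 0.05, from 2.69e-07 to 0.05 over the fits without 1 library). Of 19 hypoxia and glycolysis genes, 17 were higher (median 0.24, adjusted p = 0.000903; adjusted p = 0.879 with an estimated correlation), including the angiogenic factor gene Vegfa at 0.73 (SE 0.24). With the libraries with high fibroblast markers, lentiviral OSKM replicate 5 and lentiviral SKM replicate 1, left out together, the other 3 lists passed and the interferon list did not (adjusted p = 0.248).

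Adjusted over the list alone, 3 genes passed, against 0 over all genes tested. With no adjustment across the 31 lists, some such passes arise by chance. They were Ndrg1 (adjusted p = 0.0116), the BMP-responsive repressor gene Id4 at −2.69 (SE 0.63, adjusted p = 0.0194) and Xist, the RNA that silences an X chromosome in female cells, at −6.02 (SE 1.96, adjusted p = 0.0316), all by edgeR with Benjamini-Hochberg adjustment. Xist was at 1540, 1030 and 2070 CPM in lentiviral OSKM replicates 1, 2 and 4, at 3.73 and 8.30 CPM in replicates 3 and 5, and at most 65.8 CPM in lentiviral SKM lines. Its list had 3 tested genes. The 3 tested Y-linked genes went the other way and did not pass (Ddx3y at 3.99, SE 2.21, Uty at 3.12, SE 1.99, and Eif2s3y at 2.13, SE 2.02). Whether the sex chromosomes of the lines differ between the groups was not tested. The directional test fry called 0 lists, as did camera with an estimated correlation, each with 1 list at an unadjusted p under 0.05, where camera with the preset correlation had 6. Fry's mixed test called 0. For the BMP response, cell cycle and replication histone lists the median log2 fold change (0.12, −0.03 and 0.27) and camera's direction differed in sign, and none of them passed.

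The comparison of retroviral with lentiviral OSKM lines set lines made with the same 4 factors side by side. In retroviral lines versican (Vcan), a chondroitin sulphate proteoglycan of the extracellular matrix, fell from 129 to 8.45 CPM, a log2 fold change of −3.93 (SE 0.45, edgeR quasi-likelihood adjusted p = 0.00618 with Benjamini-Hochberg adjustment), and was lower in 5 of 5 lines. Chpf, whose product polymerises chondroitin, fell by 1.26 on the log2 scale (SE 0.18, adjusted p = 0.0164), and Cpxm1, a secreted carboxypeptidase-like gene, fell from 127 to 33.9 CPM (−1.90, SE 0.31, adjusted p = 0.0393). The interferon-induced gene Ifit2 fell from 2.43 to 0.173 CPM (−3.79, SE 0.51, adjusted p = 0.0115). Lentiviral SKM lines averaged 0.672 CPM of Ifit2, with 2.22 CPM in replicate 1 and 0.181 to 0.48 CPM in the others. The lentiviral OSKM lines thus lay above both other groups on average. Carnmt1, a carnosine methyltransferase, rose from 17.5 to 39.9 CPM (1.19, SE 0.16, adjusted p = 0.0115).

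Among the other genes that rose, Stk3, a kinase of the Hippo pathway, increased by 0.92 (SE 0.15, adjusted p = 0.03), and Pwwp2a, a chromatin protein that binds the histone variant H2A.Z, by 0.89 (SE 0.15, adjusted p = 0.0443) on the log2 scale in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The small nucleolar RNA host transcript Snhg5 rose by 0.77 (SE 0.13, adjusted p = 0.0478). Vcan lies on chromosome 13 from 89655312 to 89742509, Carnmt1 on chromosome 19 from 18670764 to 18707200 and Chpf on chromosome 1 from 75474569 to 75479307 (GRCm38). Vcan passed in 10 of 10 fits that left out 1 library, Ifit2 and Carnmt1 in 9, Chpf in 8, Cpxm1 and Pwwp2a in 3, Stk3 in 2 and Snhg5 in 1.

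Of the reprogramming factors none passed with edgeR, whereas Pou5f1 and Myc passed with DESeq2. Pou5f1 was at 74.4, 0.673, 8, 0.113 and 21.9 CPM in retroviral OSKM replicates 1 to 5, against a mean of 0.203 CPM in lentiviral OSKM lines (log2 fold change 6.68, SE 1.60, edgeR quasi-likelihood adjusted p = 0.125 with Benjamini-Hochberg adjustment). Over the alternatives its log2 fold change ran from 3.71, with voom and sample quality weights, to 7.49, and its adjusted p from 8.05e-05, with DESeq2, to 0.319. Sox2 was at 67.3 CPM in retroviral OSKM replicate 1 and 4.98 CPM in replicate 4 (4.77, SE 2.15, adjusted p = 0.342), and its log2 fold change was 1.25 without retroviral OSKM replicate 1. Over all alternatives that of Sox2 ran from 0.94 to 5.17, with adjusted p from 0.233 to 0.937. Myc averaged 171 CPM in retroviral and 74.5 CPM in lentiviral OSKM lines (1.2, SE 0.35, adjusted p = 0.178, from 0.0367 with DESeq2 to 0.451 over the alternatives), and Klf4 247 and 229 CPM (0.11, SE 0.49, adjusted p = 0.942). Adjusted over the list alone, Pou5f1 and Myc passed, against 0 of the 4 factors over all genes tested.

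Most of the called genes were pseudogenes, mostly copies of other genes. They made up 26 of the 39 called genes, 66.7% against 7.0% of all genes tested (two-sided Fisher's exact test p = 2.56e-21). Their reads are uncertain, because 22 of the 26 are at least 95% identical over 80% of their length to a more highly counted gene. Fisher's test takes genes as independent, which copies with shared reads may not be, so its p-value is uncertain. Most of the called pseudogenes carry clone names, which the rule for named genes leaves out. Among the others, Rps19-ps6 rose by 2.77 (SE 0.37, edgeR adjusted p = 0.0115), Rpl3-ps2 by 2.06 (SE 0.26, adjusted p = 0.0115) and Rpl14-ps1 by 1.18 (SE 0.17, adjusted p = 0.0164) on the log2 scale. Rpl9-ps6, which the annotation lists as protein coding, rose by 1.35 (SE 0.23, adjusted p = 0.0434). Rpl15-ps2 fell by 5.48 (SE 0.86, adjusted p = 0.03), Rpsa-ps12 fell by 3.30 (SE 0.28, adjusted p = 0.000745), Rpsa-ps9 fell by 3.28 (SE 0.31, adjusted p = 0.00153) and Rps13-ps1 fell by 1.81 (SE 0.31, adjusted p = 0.0478). Rpl3-ps2, Rpsa-ps12 and Rpsa-ps9 passed in 10 of 10 fits that left out 1 library, Rps19-ps6 in 8, Rpl14-ps1 in 5, Rpl15-ps2 in 3, and Rpl9-ps6 and Rps13-ps1 in 1.

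In all, 39 of 15483 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 17 higher and 22 lower in retroviral lines, of which 12 are annotated as protein coding (7 higher, 5 lower). With library size as the only scaling the split was 9 higher and 19 lower. At an unadjusted p under 0.05 there were 2238 genes, where chance gives 774, and the groups did not overlap for 616 genes, 3.98% against 0.79% by chance. Spearman correlations between libraries averaged 0.93 within retroviral OSKM, 0.952 within lentiviral OSKM and 0.933 between them. The within-minus-between difference of 0.0077, reached by 3 of 126 regroupings (one-sided exact permutation p = 0.0238), thus came from the lentiviral lines. On simulated counts for these 15483 genes the test recovered 13.1%, 54.3% and 65.2% of 2-, 4- and 8-fold changes. The count fell to 23, 21 and 15 without retroviral OSKM replicates 1, 2 and 4 and to 15, 17 and 21 without lentiviral OSKM replicates 1, 2 and 4, was 101 without retroviral OSKM replicate 5, 7 without the 3 libraries in doubt (retroviral OSKM replicates 1 and 3 and lentiviral OSKM replicate 5), 3 among protein-coding genes alone, 63 with voom, 225 with voom and sample quality weights and 623 with DESeq2. Vector, clonal derivation and library series divide these lines in the same way, so their contributions cannot be told apart.

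**Figure D4:**
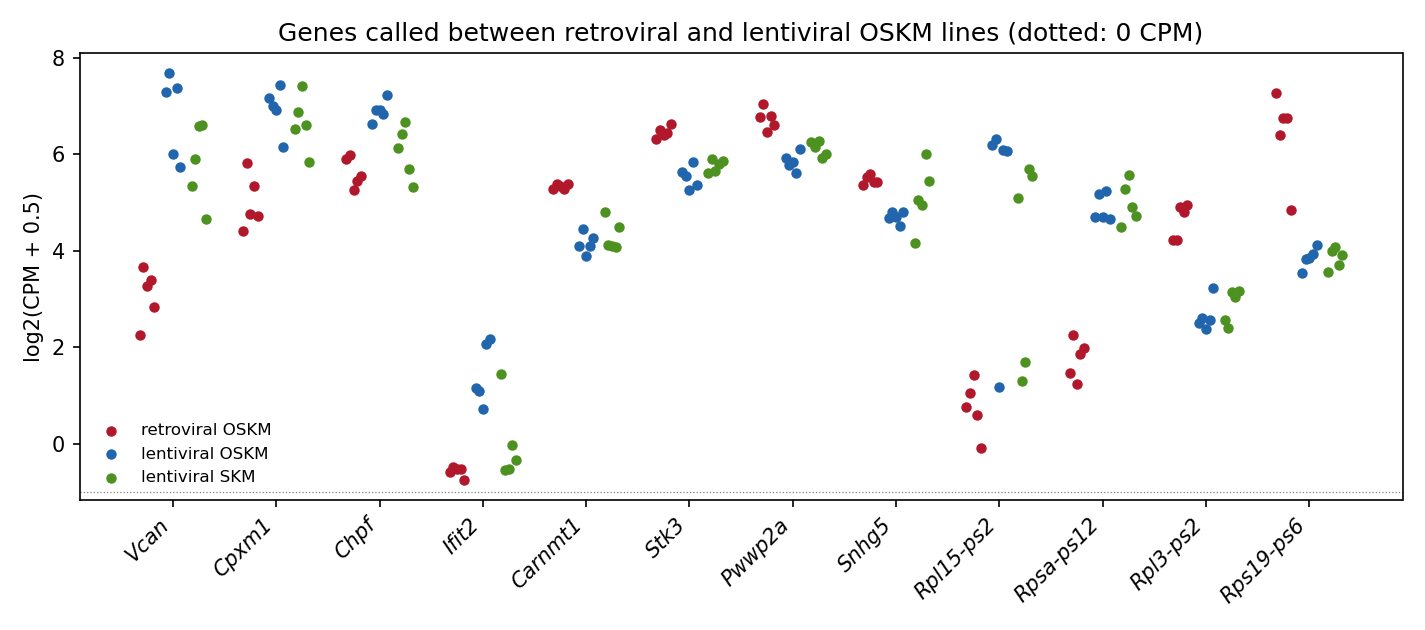
Level of 12 genes as log2(CPM + 0.5) in each retroviral OSKM, lentiviral OSKM and lentiviral SKM line, with 1 point per line (n = 5 per group). Vcan averaged 8.45 CPM in retroviral and 129 CPM in lentiviral OSKM lines, and Ifit2 averaged 0.173 and 2.43 CPM.

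Of 30 gene lists tested, camera called 7. All 20 genes of cholesterol synthesis were lower in retroviral lines (median log2 fold change −0.62, adjusted p = 5.46e-09; adjusted p = 0.486 with an estimated correlation), with Dhcr7 at −1.16 (SE 0.28) and Hsd17b7 at −1.02 (SE 0.24), genes for enzymes of the pathway. Of 18 interferon response genes, 17 were lower (median −1.47, adjusted p = 8.54e-09; adjusted p = 0.486 with an estimated correlation), and 11 passed when adjusted over the list alone, against 1, Ifit2, over all genes tested. Of 20 Myc target genes, 16 were higher (median 0.39, adjusted p = 0.000234; adjusted p = 0.486 with an estimated correlation), led by the nucleolar chaperone gene Npm1 at 1.41 (SE 0.26), and 5 passed over the list alone. Of 18 hypoxia and glycolysis genes, 17 were higher (median 0.60, adjusted p = 0.00218; adjusted p = 0.486 with an estimated correlation), with Vegfa at 1.04 (SE 0.29). Ldha belongs to both the Myc target and the hypoxia list. The cholesterol, interferon and hypoxia lists had the same directions in lentiviral SKM against lentiviral OSKM lines. Both comparisons use the same lentiviral OSKM libraries, so these directions are not independent. Without the 3 libraries in doubt the hypoxia list did not pass (adjusted p = 0.0671).

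The other called lists concern cell type and histones. Of 19 parietal endoderm genes, 18 were lower in retroviral lines (median −0.58, camera adjusted p = 0.005; adjusted p = 0.587 with an estimated correlation), with Lama1 at −0.68 (SE 0.49) and Lamc1 at −0.75 (SE 0.53). By edgeR, 0 of the 19 genes had an unadjusted p under 0.05. Retroviral OSKM replicate 3 had Lamc1 at 1050 CPM, against 9810 to 17400 CPM in the others of its group, and the list passed in 10 of 10 fits that left out 1 library. Of 13 fibroblast genes, 10 were lower (median −1.33, adjusted p = 0.0466; adjusted p = 0.587 with an estimated correlation), with the matrix protease gene Mmp2 at −3.26 (SE 0.61). The fibroblast median was 4.32 in lentiviral OSKM replicate 5 and at most −0.21 in the other lentiviral OSKM lines, and the call was lost without retroviral OSKM replicate 2, 4 or 5 or lentiviral OSKM replicate 5 (adjusted p from 0.00193 to 0.254 over the fits without 1 library). Of 7 replication histone genes, 5 were higher (median 0.87, adjusted p = 0.0466; adjusted p = 0.587 with an estimated correlation), a call lost without retroviral OSKM replicate 2 or lentiviral OSKM replicate 2, 4 or 5 (adjusted p from 0.0147 to 0.182) and without the 3 libraries in doubt (0.0671), and all of these genes except Hist1h2bc averaged 2.99 CPM or less in both groups. Most replication histone transcripts lack a poly(A) tail.

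Camera with an estimated correlation and directional fry each called 0 lists (2 and 5 at an unadjusted p under 0.05), and mixed fry, which asks whether genes of a list change in either direction, called 4 (Myc targets, adjusted p = 0.0011; interferon response, 0.00784; cholesterol synthesis, 0.0385; replication histones, 0.0407). Of 100 regroupings of the same lines, 45 gave at least 7 lists. The XEN regulators were not distinguished, with 9 of 12 lower and a median of −0.17 (camera adjusted p = 0.191). For the pluripotency list the median log2 fold change was 0.22 while camera's direction was down, and for the germline list it was −0.39 with camera's direction up. The X inactivation and posterior Hox lists had medians of 0.27 and 0.19 with camera's direction down, and none of these 4 lists passed. Adjustment over the list alone makes no allowance for the number of lists. Over 9 lists, 28 entries passed when adjusted over the list alone, against 1 over all genes tested, with Pou5f1 counted in both the reprogramming factor and the pluripotency list. Xist was among them (−8.50, SE 1.73), at 0.377 to 5.54 CPM in retroviral OSKM lines and, in lentiviral OSKM lines, at 1030 to 2070 CPM in 3 and at 3.73 and 8.30 CPM in the others.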

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

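In 23 of 220 tested groups of 5 lines, 1 line stood apart from the other 4 by a gap of more than 0.71 of the whole range, where chance gives about 11. Of the tests of explanations here, the match of pseudogenes to other genes was fixed before its result was seen, and those on depth, library series, cell type and gene loss were chosen only after the result was seen.

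The genes that differed between retroviral and lentiviral OSKM lines included 26 pseudogenes among 39. Greater depth of the lentiviral libraries is argued against, since 25 of the 26 still passed after thinning to the mean retroviral depth. Library series alone is argued against for 2 of them. Rpl15-ps2 was at 0.442 to 2.19 CPM in retroviral lines, 1.76 CPM in lentiviral OSKM replicate 3, and 1.96 and 2.74 CPM in lentiviral SKM replicates 2 and 3. In the other lentiviral lines it was at 33.8 to 79.2 CPM. Gm10020, chosen after its values were seen, divided the lines in the same way, so the 2 may not be independent. These values argue equally against vector alone and derivation alone, which divide the lines as series does. For the other 24, series, vector and derivation cannot be told apart, because no lentiviral line reached the retroviral range. Reads shared with near-identical genes stay open: 84.6% of the called pseudogenes have such a match against 78% of the 1061 not called (one-sided Fisher's exact test p = 0.298), and a strain variant against the reference was not tested. Reads with no unique alignment took 4.93% to 7.35% of entries in retroviral and 4.15% to 4.97% in lentiviral OSKM libraries. Reads not aligned took 3.55% to 6.91% against 7.41% to 10.38%. Whether this difference in alignment bears on the pseudogene counts was not tested.

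Col4a1 and Col4a2, neighbouring genes for the chains of basement membrane collagen on chromosome 8 (11198423 to 11312826 and 11312805 to 11449287), were at 62.1 and 41.4 CPM in lentiviral OSKM replicate 5 and at 55.3 and 47.5 CPM in retroviral OSKM replicate 1, against 5100 to 32400 and 2450 to 13200 CPM in the other lines. Fewer parietal endoderm cells are argued against as the whole cause. Over both lines 16 other parietal genes changed by a median of −0.29 (SD 0.93), while Col4a1 changed by −7.38 on average (log2). Single genes varied more. In retroviral OSKM replicate 1 and lentiviral OSKM replicate 5, Thbd changed by −2.6 and −4.44, Nid1 by 0.02 and −2.66 and Fst by 1.73 and −2.42. Vim rose in both, by 0.96 and 0.4. Both lines also stood apart in their groups for high fibroblast medians (1.32 and 4.32). Loss of all copies of the wider region is argued against by 7 expressed genes within 1 Mb, with medians of −0.49 (SD 0.66) and −0.5 (SD 0.75). Loss of 1 of 2 copies of the region is argued against as the whole cause, since it gives a change of −1, whereas the smallest change of the pair was −6.33 (SD of the other lines of a group at most 1.25). A deletion limited to the gene pair and silencing were not tested, and the lines come from different groups, so the design gives no group difference to set against these.

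Retroviral OSKM replicate 3 was low for the endoderm genes Foxa2 (2.6 CPM, others of its group 142 to 195), Gata6 (107 CPM, 314 to 484) and Dab2 (233 CPM, 779 to 1150) and the laminin gene Lamc1 (1050 CPM, 9810 to 17400). Its haematopoietic median was −0.23 (others −0.77 to −0.69). Lentiviral OSKM replicate 5 had a fibroblast median of 4.32 (others −0.75 to −0.21), Thy1 at 40 CPM (0.029 to 0.122) and Cdx2 at 13.7 CPM (0 to 0.226). Rpl3-ps2 was at 8.83 CPM in it (4.71 to 5.6). Retroviral OSKM replicate 1 had a fibroblast median of 1.32 (others −0.92 to −0.58), a neural median of 1.36 (−0.82 to −0.64) and Thy1 at 0.86 CPM (0 to 0.0232). In retroviral OSKM replicate 4 Cdx2 was at 0.735 CPM (0 to 0.139). Retroviral OSKM replicate 5 had 46995817 counts in genes (34916933 to 37875911) and Ndrg1 at 417 CPM (184 to 223). Lentiviral OSKM replicate 1 had a pluripotency median of 0.18 (−0.74 to −0.54), and lentiviral OSKM replicate 3 had Rpl15-ps2 at 1.76 CPM (66.4 to 79.2). Lentiviral SKM replicate 1 had Ifit2 at 2.22 CPM (0.181 to 0.48), Rpl14-ps1 at 103 CPM (152 to 177) and Rpsa-ps9 at 10.6 CPM (18.8 to 21.7). Lentiviral SKM replicate 5 had Zeb1 at 32.8 CPM (45.6 to 51.3) and a haematopoietic median of 0.08 (−0.84 to −0.59).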

How the results depend on the processing

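Leaving out libraries in doubt, protein-coding genes only and thinning were chosen after the result was seen, and causes were not tested unless fewer libraries or genes enter by construction. Between lentiviral SKM and OSKM lines DESeq2 called 44 genes and the other alternatives 0, as did each fit without 1 library. Its 4 lists became 0 with camera's estimated correlation, 0 with directional fry and 3 to 5 without 1 library. Chance cannot be excluded for the 4 lists, which 82 of 100 regroupings reached (highest other 12). For 0 genes regroupings decide nothing, since all 100 reach that count by construction (highest other 2). Pou5f1 reversed with voom (−0.08) and ranged from −0.37 to 1.02 without 1 library (−0.1 without lentiviral OSKM replicate 2, −0.04 without lentiviral SKM replicate 4), and Myc from −0.03 to 0.28. Between retroviral and lentiviral OSKM lines the 39 genes became 623 with DESeq2 (38 shared), 63 with voom (37 shared), 225 with sample quality weights (37 shared), 24 without a filter, 155 with all 15 libraries in one fit (38 shared), 7 without the libraries in doubt, 3 with protein-coding genes only, 7 at adjusted p under 0.01 and 15 to 101 without 1 library (15 without retroviral OSKM replicate 4, 101 without replicate 5). They numbered 36 with robust edgeR, 28 with library size only and 43 after thinning (37 shared). Chance is argued against for this count, as 1 of 100 regroupings, the real one, reached it (highest other 1), the smallest share they can give. Regroupings take the lines as exchangeable, which is uncertain because the retroviral clones may share a preparation. Chance cannot be excluded for the 7 lists, which 45 regroupings reached (highest other 12). Those lists became 0 with the estimated correlation, 0 with directional fry and 6 to 11 without 1 library (11 without retroviral OSKM replicate 5). Klf4 was −0.15 with voom, −0.34 with sample quality weights and −0.16 to 0.38 without 1 library (−0.13, −0.01 and −0.02 without retroviral OSKM replicate 1 and lentiviral OSKM replicates 4 and 5). The replicate numbers do not pair the lines: correlations of same-numbered lines ran from −0.166 to 0.268 and from −0.186 to 0.051, with 1 and 0 of 5 lines closest to its own number. The replicate block gave 0 genes and 7 lists in the lentiviral comparison, 3 genes and 8 lists in the retroviral one, and Klf4 at −0.1. XEN regulators minus pluripotency was 8.85, 7.05 and 5.71 in retroviral OSKM, 9.52, 7.52 and 6.23 in lentiviral OSKM and 10.11, 7.97 and 6.39 in lentiviral SKM lines with a pseudocount of 0.1, a pseudocount of 1 and the mean over members, and 7.6 to 8.01, 8.22 to 8.38 and 8.58 to 8.96 without 1 library. Of 337 values for named genes in the lentiviral comparison 322 kept their direction and side of the threshold, 10 passed with DESeq2 and 5 reversed. Of 551 in the retroviral comparison 405 did so, 137 no longer passed, 2 passed with DESeq2 and 7 reversed. Low genes in the shallower retroviral libraries are limited by depth.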

Other observations

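The genes of this part were chosen after their values were seen, and the bounds that define a chromosome shift were set after the medians were seen. Imprinted genes, expressed from 1 parental allele, differed widely between lines. Igf2r, the receptor that clears IGF2, was at 205 to 391 CPM in 6 lines and at 15.8 to 35.0 CPM in the other 9. The non-coding RNAs Meg3 and Rian, from 1 imprinted domain, reached 373 and 361 CPM in lentiviral OSKM replicate 3 and 49.1 and 61.3 CPM in retroviral OSKM replicate 1, and were at 0 in lentiviral SKM replicate 3. H19 and Igf2 were at 1820 and 629 CPM in retroviral OSKM replicate 3. Within the lentiviral groups the imprinted list had a median SD of 1.23 log2 units against 0.40 for random lists of matched expression, above all 10000 of them, as were 11 of the 31 lists. Myc targets lay at percentile 28.28 with a median SD of 0.27.

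Xist was at 1540, 1030 and 2070 CPM in lentiviral OSKM replicates 1, 2 and 4, at 65.8 CPM in lentiviral SKM replicate 4 and at 8.30 CPM or less in the other lines. The Y-linked gene Ddx3y was at 48.3, 42.2 and 103 CPM in lentiviral SKM replicates 1, 3 and 4, at 12.2 CPM in lentiviral OSKM replicate 3 and at 5.91 CPM or less elsewhere. In lentiviral SKM replicate 4 the Y-linked Eif2s3y and Kdm5d were at 0.132 and 0 CPM, while Uty was at 12.8 CPM. Retroviral OSKM replicate 3, low in Foxa2, had the endothelial genes Pecam1, Tie1 and Erg at 136, 72.9 and 57.2 CPM, against at most 23.1, 4.02 and 6.24 CPM in the other lines, and the X-linked homeobox gene Rhox5 at 536 CPM. The fibroblast collagen gene Col1a1 was at 196 CPM in lentiviral OSKM replicate 5, 150 CPM in lentiviral SKM replicate 1, 51.5 CPM in retroviral OSKM replicate 1 and 10.4 CPM in lentiviral SKM replicate 2, and below 1 CPM in the other lines.

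Genes of whole chromosomes were shifted together in single lines. Of 300 pairs of line and chromosome, 17 passed, 10 upward and 7 downward, in 9 lines. The largest of those that passed were chromosomes 12 and 14 in retroviral OSKM replicate 5 (median log2 shift 0.64 and 0.55). Next were chromosome 16 in lentiviral OSKM replicate 5 (−0.52) and chromosome 14 in lentiviral SKM replicate 3 (0.48). In all cells, 3 copies for 2 give 0.58 and 1 copy for 2 gives −1. No downward shift reached −1. Chromosome 4 in lentiviral OSKM replicate 4 had a median of −0.51 over 551 genes but did not pass the rule on segments. Chance runs of neighbouring genes are argued against, since the most shifts in any of 1000 shuffles of 20-gene blocks was 1, and so are GC content and transcript length, since 15 shifts remained after regression on both. A gain or loss of chromosomes in part or all of the cells of these lines may be the source, which is a hypothesis that counts per gene cannot settle.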
